A study of Mus musculus with 6 samples.

How the data were processed

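RNA was sequenced from macrophages differentiated from mouse bone marrow, all from animals homozygous for the GRdim receptor mutation. Per the labels' protocols, the cells were grown with conditioned medium of L-929 fibroblasts, moved to serum-free medium, treated with 1 µM dexamethasone overnight where the group calls for it, and given LPS for 6 h on the next day. Total RNA went into stranded paired-end libraries. There were 6 samples, 3 in the LPS group and 3 in the LPS+Dex group, grouped by their titles.

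The authors deposited 1 table of 23235 genes that compares the groups. Its expression values are FPKM (fragments per kilobase of transcript, scaled to the library total), 1 value per gene and group, per the file headers. How replicates were combined and how libraries were scaled to each other are not given in the sources used here. The log2 fold change in the deposited table is that of LPS+Dex over LPS, and where a group is at 0 it holds a stand-in for infinity, which was not used. The deposited test statistic is a score with the opposite sign of the fold change. Its 2-sided normal tail gives the deposited p-value, and the q-value is the Benjamini-Hochberg adjustment over the 11755 genes with a test, as checked on the deposited values. The tools named in the submitters' processing notes are CASAVA, TopHat 1.4.1 and Cufflinks 2.0.2, with build mm9, and the notes used here give neither their roles nor their order. The gene annotation is not given in the sources used here. FPKM scales with the assumed transcript length and with the total of each library, so a change in a few abundant genes shifts all others slightly the other way.

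The table's status column leaves 11278 genes without a test for low signal (none above 0.110 FPKM), 152 marked LOWDATA, 20 whose test failed and 30 marked HIDATA that are listed at 0 in at least 1 group. Genes marked LOWDATA include abundant ones, such as a joined row of Gm9846 and Rps27 at 677 FPKM in LPS. No value per sample was in the table, so replicates could not be compared with each other and no test of its own was run on samples. Library depth is unknown. Among 3216 low genes with both values above 0, the most frequent ratio of the groups, at 3 decimals, occurred 14 times, so no common step from which relative depth could be read was seen. In 89 rows several symbols share a value, and 25 symbols had been turned into dates, 9 of them in called rows. These counted among the calls but were not named.

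A gene was called higher or lower when the authors' q was under 0.05 and the fold change above or below 0, which gives the same calls as the authors' own column of significance. The standard error of a log2 fold change was taken as its absolute ratio to the deposited test statistic and is named the implied standard error (SE). It had quartiles of 0.0541 and 0.130. These values carry no SD or n of their own.

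The design, the alternatives, the rule for named genes and 26 gene lists were fixed before the data were examined. The lists cover glucocorticoid-induced genes, LPS-induced cytokines, chemokines, interferon-stimulated genes, Toll-like receptor and NF-kB signalling, AP-1 and immediate early genes, inflammatory effectors, antigen presentation, alternative activation, sterol synthesis, lipid handling, glycolysis, the circadian clock, the receptor and its cofactors, the cell cycle, the stress response, adhesion and ribosomal proteins. Others hold markers of macrophages, neutrophils, T and NK cells, B cells, dendritic cells, stromal cells, erythroid cells, and mast cells and basophils. Of the list genes, Eno1, Hba-a1 and Hbb-b1 share a row with another symbol and were left out of the counts, and Spi1 and Ly6g were not analysed here under these symbols. For each list the members called were counted over all genes tested and adjusted over the list alone. Where at least 3 members were tested, the list's median log2 fold change was placed among the medians of 10000 random lists of the same size, matched on mean FPKM in 20 bins, and its counts of called genes among theirs. The percentile describes these libraries and is not a p-value across genes.

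The genes to be named were chosen as Nr3c1 and other genes fixed as canonical, the 8 largest called rises and the 8 largest called falls with at least 1 FPKM in a group, both values above 0 and a single symbol, and for each list the called member with the largest change in each direction and the uncalled member with the highest mean. Not all genes so chosen are named in the report. Other list members were chosen as examples after their values were seen. The split of MHC genes into classes and a scan of gene families by symbol stem were also chosen after the values were seen. That scan used 2000 random lists for each of 199 stems with at least 8 tested genes.

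Alternatives were a q of 0.01 or 0.1, Bonferroni adjustment, recomputed Benjamini-Hochberg adjustment, changes of at least 1.5-fold or 2-fold, minimum values of 1 or 5 FPKM, single symbols only, log2(FPKM + 1) or log2(FPKM + 0.1) in place of the deposited fold change, unmatched random lists, and centring on the median of genes with at least 1 FPKM. Removal of a lowess trend (span 0.3) on log10 mean FPKM, transcript length or GC content was added after seeing the data. Lengths and GC content came from the longest transcript of each symbol in GENCODE vM21, matched by current or older symbol for 98.6% of tested genes, with no coordinates taken from it. Standard errors of slopes and medians in the closing part come from 1000 bootstrap draws over genes.

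The calling step with the trend removed was tested on simulated data built on the 11745 genes with both values above 0. Of 50 genes changed 1.25-fold, 1.5-fold, 2-fold and 4-fold in each case, it recovered 70%, 100%, 96% and 98%, and it called 0.113% of unchanged genes, against 7.48% when the trend was left in. The simulated noise was drawn from the same implied SE that the test uses, so these rates cannot show whether that error is right. Far fewer genes were changed in the simulation than the 42.9% called in the data, where removal of a trend may work less well. Of 100 random lists of 20 genes in the simulation, 7% fell outside the central 95%, and all of 100 lists shifted by 0.3 were found. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.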

Results

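Gene expression was measured by RNA sequencing in primary macrophages grown from the bone marrow of mice homozygous for GRdim, a mutant glucocorticoid receptor whose dimerization is impaired. The libraries form 2 groups of 3 samples, cells given lipopolysaccharide (LPS) for 6 h and cells that had also been given 1 µM dexamethasone (Dex) overnight. LPS is a bacterial cell wall component that activates macrophages through Tlr4, and Dex is a synthetic glucocorticoid. The comparison of LPS+Dex with LPS asks which genes differ with the hormone when the receptor's dimer contact is mutated. Wild-type cells and cells without LPS were not analysed here, so no response can be called kept or lost through the mutation. All expression levels, fold changes, test statistics and q values are those of the authors' deposited table, which gives 1 FPKM value per group and no value per sample. The labels do not say whether the 3 samples of a group came from separate animals or cultures. How the deposited test takes its error from these samples is not given in the sources used here. Any spread that it measures may be technical. The sequencing depth of each library is unknown, because the table holds no counts.

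In the GRdim cells, 8 of 17 tested glucocorticoid-induced genes were higher with Dex and 13 of 16 tested LPS-induced cytokine genes were lower, by the calls of the authors' deposited table. Tsc22d3, which encodes the anti-inflammatory leucine zipper protein GILZ, rose from 3.99 to 11.0 FPKM (log2 1.47, implied SE 0.075). The kinase gene Sgk1 rose from 39.1 to 90.8 FPKM (log2 1.22, implied SE 0.055). Il12b, which encodes the shared subunit of IL-12 and IL-23, fell from 27.4 to 6.54 FPKM (log2 −2.07, implied SE 0.061). Il6 fell from 409.8 to 205 FPKM (log2 −1.0, implied SE 0.049). Of 22 cell cycle genes 16 rose, and of 18 genes of alternative activation and scavenging 10 rose and 5 fell. Of 6 MHC class II genes, set apart after the values were seen, 5 fell, as did 3 of 4 dendritic cell markers.

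Of 23235 genes in the authors' deposited table, 11755 (50.6%) had a test, and 5045 of these (42.9%) passed the authors' threshold of q under 0.05. Of the genes that passed, 2077 were higher and 2968 (58.8%) lower in LPS+Dex. Most changes were small, with a median of 1.26-fold, and 75.5% of called genes with both values above 0 changed by less than 1.5-fold. At 2-fold or more, 262 genes were higher and 260 lower, so the surplus of lower calls lay among the smaller changes. At 4-fold or more, 29 genes were higher and 49 lower. The standard error implied by the deposited test statistic had a median of 0.0714 on the log2 scale. A damped value is given beside a called change that was over 1.5 times smaller on the log2(FPKM + 1) scale, which tempers the changes of scarce genes.

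The largest rises with at least 1 FPKM in a group began with Cd55 (chromosome 1, 132335606 to 132359317, mm9 coordinates as the table lists them), which encodes decay-accelerating factor and rose from 0.139 to 25.8 FPKM (log2 7.54, implied SE 0.27, damped 4.55). Its paralog Daf2 was too low for a test, at 0.0814 FPKM in LPS+Dex. Cxcl13, a B cell chemoattractant (chromosome 5, 96385957 to 96390087), rose from 0.156 to 6.38 FPKM (log2 5.35, implied SE 0.39, damped 2.67). Cd207, which encodes the lectin langerin, rose from 0.239 to 3.40 FPKM (log2 3.83, implied SE 0.28, damped 1.83). Klhl6 rose from 2.24 to 25.5 FPKM (log2 3.51, implied SE 0.079). Fstl1 rose from 0.216 to 1.91 FPKM (log2 3.15, implied SE 0.19, damped 1.26). Cbr2, a carbonyl reductase gene, rose from 2.68 to 23.0 FPKM (log2 3.10, implied SE 0.11). The protease inhibitor gene Serpine2 rose from 2.55 to 19.4 FPKM (log2 2.93, implied SE 0.081). Ear11, of the eosinophil-associated ribonuclease family, also rose, from 0.00711 to 1.21 FPKM (log2 7.41, implied SE 2.53, damped 1.13); its LPS value lies near the floor, its error is wide (q = 0.00982), and reads shared with near-identical family members cannot be excluded. Lyve1 and Btg3, chosen after their values were seen, were listed at 0 in LPS and at 0.269 and 0.213 FPKM in LPS+Dex.

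Among the largest falls in the authors' deposited table, Ccl22, a chemokine for regulatory T cells (chromosome 8, 97269583 to 97275288), fell from 185 to 32.5 FPKM (log2 −2.51, implied SE 0.048). Pgf, encoding placental growth factor, fell from 1.13 to 0.110 FPKM (log2 −3.36, implied SE 0.39, damped −0.94). The nuclear receptor gene Nr4a3 fell from 1.36 to 0.183 FPKM (log2 −2.89, implied SE 0.28, damped −1.0). The neutrophil chemokine Cxcl5 fell from 2.11 to 0.299 FPKM (log2 −2.82, implied SE 0.23, damped −1.26). Lrrc32, which encodes the TGF-beta docking receptor GARP, fell from 3.98 to 0.598 FPKM (log2 −2.73, implied SE 0.11, damped −1.64). The pantetheinase gene Vnn3 fell from 2.89 to 0.423 FPKM (log2 −2.77, implied SE 0.19, damped −1.45). The glutathione transferase gene Gsta3 fell from 1.52 to 0.282 FPKM (log2 −2.43, implied SE 0.40, damped −0.98). The transcriptional repressor gene Zbtb32 fell from 7.54 to 1.53 FPKM (log2 −2.30, implied SE 0.10).

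**Figure D1:**
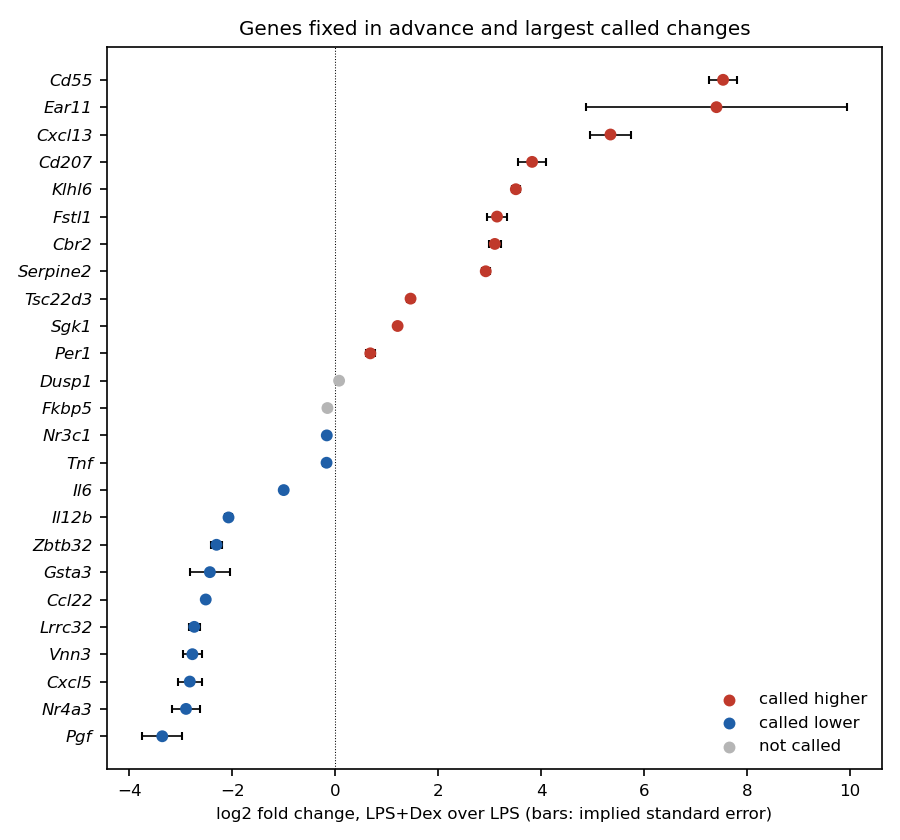
Log2 fold change of LPS+Dex over LPS (horizontal axis) for the genes fixed in advance and the 8 largest called rises and falls, from the authors' deposited table. Points are single deposited values coloured by call and bars are the implied standard error, which is widest for Ear11 at 2.53.

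The receptor gene itself, Nr3c1, fell slightly, from 32.0 to 28.6 FPKM (log2 −0.16, implied SE 0.048) with q = 0.00284, and relative to genes of the same expression level its change was −0.089 and no longer called. Of 17 tested members of the list of glucocorticoid-induced genes in the authors' deposited table, 8 rose, 2 fell and 7 did not pass; adjusted over the list alone, 8 rose and 3 fell. Besides Tsc22d3 and Sgk1, the clock gene Per1 rose from 2.19 to 3.52 FPKM (log2 0.69, implied SE 0.090). The haptoglobin-hemoglobin scavenger receptor gene Cd163 rose from 0.0632 to 0.241 FPKM (log2 1.93, implied SE 0.33, damped 0.22). Fkbp5, an immunophilin gene that is a standard glucocorticoid target, was not called at 3.71 and 3.35 FPKM (log2 −0.15, q = 0.0765). Dusp1, which encodes a phosphatase that inactivates MAP kinases, was not called at 180.2 and 190.3 FPKM (log2 0.079, q = 0.213), nor was Anxa1 at 994 and 1003 FPKM (log2 0.012, q = 0.907). Ddit4 fell from 1.18 to 0.779 FPKM (log2 −0.60, implied SE 0.18, damped −0.29). Errfi1 fell from 2.04 to 1.4 FPKM (log2 −0.54, implied SE 0.098, damped −0.34). The list's median log2 fold change of 0.079 lay at percentile 94.6 of random lists matched on expression, inside their central 95%. By counts the list stood apart, with more rises than matched lists (mean 2.70, percentile 99.9) and fewer falls (mean 5.47, percentile 2.28). The percentile of the median was 98.8 on the log2(FPKM + 1) scale and 88.7 against unmatched lists. With the trend on expression level removed it was 99.9 and the median 0.24, with 11 genes higher and 4 lower, and Dusp1 and Anxa1 were then called higher and Fkbp5 lower.

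Of 16 tested cytokine genes induced by LPS in the authors' deposited table, 13 fell, 1 rose and 2 did not pass, with the same counts adjusted over the list alone. The list's median was −0.75, below all 10000 matched random lists, whose median was −0.089. The growth factor gene Csf2 fell from 0.208 to 0.0313 FPKM (log2 −2.73, implied SE 0.95, damped −0.23) from a low level. Ifnb1, which encodes interferon beta, fell from 1.37 to 0.305 FPKM (log2 −2.16, implied SE 0.38, damped −0.86). Il1a fell from 1335 to 588 FPKM (log2 −1.18, implied SE 0.068). Tnf fell by little, from 1042 to 929.6 FPKM (log2 −0.16, implied SE 0.069), and passed narrowly (q = 0.0414); centred on the median of genes with at least 1 FPKM it was −0.14 and not called, and with the trend on expression level removed it was 0.045. Csf3, the granulocyte growth factor gene, rose from 11.3 to 18.7 FPKM (log2 0.72, implied SE 0.064). Il10, which encodes an anti-inflammatory cytokine, was not called at 32.5 and 32.5 FPKM (log2 −0.0011, q = 0.989). Il1b and Il1rn had no test, being listed at 0 in LPS and at 2793 and 1074 FPKM in LPS+Dex.

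Among 16 tested chemokine genes in the authors' deposited table, 11 fell, 3 rose and 2 did not pass, and the counts adjusted over the list alone were equal. The median was −0.60, again below all matched random lists. Ccl24, an eosinophil chemoattractant, fell from 7.97 to 1.69 FPKM (log2 −2.24, implied SE 0.12). Cxcl10, an interferon-induced T cell chemoattractant, fell from 3077 to 1747 FPKM (log2 −0.82, implied SE 0.084). The neutrophil chemoattractant Cxcl2 rose from 585 to 910.4 FPKM (log2 0.64, implied SE 0.060), as did Cxcl1, from 275 to 419 FPKM (log2 0.61, implied SE 0.051). The monocyte chemoattractant Ccl2 rose from 2385 to 2738 FPKM (log2 0.20, implied SE 0.074). Ccl4 was not called at 2681 and 2475 FPKM (log2 −0.12, q = 0.157). Ccl5 was listed at 0 in LPS and at 7833 FPKM in LPS+Dex, and Ccl9 at 0 in both groups, so neither had a test.

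Interferon-stimulated genes fell together but by little in the authors' deposited table. Of 27 tested, 24 fell, 1 rose and 2 did not pass; adjusted over the list alone, 26 fell and 1 rose. The median was −0.27 against −0.17 for matched random lists, at percentile 0.19. Oasl1 fell from 897 to 548 FPKM (log2 −0.71, implied SE 0.066). Ifit1 fell from 952 to 647 FPKM (log2 −0.56, implied SE 0.074). In contrast, Oas2 rose from 52.2 to 58.2 FPKM (log2 0.16, implied SE 0.049). Oas1a was not called at 221 and 205 FPKM (log2 −0.11, q = 0.0749). These genes are abundant, and abundant genes of any kind tended to be lower in LPS+Dex; with the trend on expression level removed, the median was −0.11, 10 were lower and 1 higher.

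Of 28 genes of Toll-like receptor and NF-kB signalling in the authors' deposited table, 19 fell, 2 rose and 7 did not pass, and the counts adjusted over the list alone were equal. The median was −0.26, at percentile 0.13, and with the trend on expression level removed it was −0.11, with 14 lower and 6 higher. Socs1, a feedback inhibitor of cytokine signalling, fell from 99.3 to 41.4 FPKM (log2 −1.26, implied SE 0.049). Tnip3 fell from 201 to 102 FPKM (log2 −0.98, implied SE 0.053). The NF-kB subunit gene Rel fell from 18.9 to 10.3 FPKM (log2 −0.88, implied SE 0.055). Irak3, an inhibitor of Toll-like receptor signalling, rose from 51.0 to 56.9 FPKM (log2 0.16, implied SE 0.048), and Tnip1 rose from 191 to 209.9 FPKM (log2 0.13, implied SE 0.054). Cd14, the LPS co-receptor gene, was not called at 1753 and 1948 FPKM (log2 0.15, q = 0.145), and was called higher once the trend on expression level was removed.

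Of 13 AP-1 and immediate early genes in the authors' deposited table, 8 fell, 2 rose and 3 did not pass, with the same counts adjusted over the list alone. Their median was −0.44, at percentile 0.01, and −0.24 on the log2(FPKM + 1) scale. Egr2 fell from 2.65 to 1.32 FPKM (log2 −1.0, implied SE 0.096, damped −0.65). The stress-response factor gene Atf3 fell from 487 to 302 FPKM (log2 −0.69, implied SE 0.056). Jun rose from 13.2 to 32.8 FPKM (log2 1.32, implied SE 0.051). Fosl2 rose from 13.9 to 22 FPKM (log2 0.67, implied SE 0.049), while Batf was not called at 110.1 and 106 FPKM (log2 −0.051, q = 0.436). Inflammatory enzymes and effectors went both ways, with 5 of 16 higher, 8 lower and 3 not passing; adjusted over the list alone, 6 were higher and 8 lower. Lcn2, which encodes an iron-siderophore binding protein, rose from 176 to 430.2 FPKM (log2 1.29, implied SE 0.051). The matrix protease gene Mmp9 fell from 2.68 to 0.806 FPKM (log2 −1.73, implied SE 0.11, damped −1.03). Cybb was not called at 671 and 618 FPKM (log2 −0.12, q = 0.301). The median of this list, −0.14, lay at percentile 58.6 of matched random lists and was 0.035 with the trend on expression level removed, although more genes rose than in matched lists (mean 1.87, percentile 98.4). Nos2, Irg1 and Saa3 were listed at 0 in both groups, and Ptgs2 at 0 in LPS and at 246 FPKM in LPS+Dex.

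Antigen presentation and costimulation genes fell in the authors' deposited table, with 15 of 20 lower, 1 higher and 4 not passing; adjusted over the list alone, 16 were lower and 1 higher. The median was −0.24, at percentile 0.52. It was −0.11 with the trend on expression level removed, with 8 lower. Ciita, the transactivator of MHC class II genes, fell from 1.34 to 0.295 FPKM (log2 −2.18, implied SE 0.20, damped −0.85). The invariant chain gene Cd74 fell from 163 to 43.8 FPKM (log2 −1.90, implied SE 0.052). H2-Aa fell from 10.1 to 3.20 FPKM (log2 −1.66, implied SE 0.10). Split after the values were seen, the 6 class II genes had a median of −1.46 with 5 called lower, H2-DMa being the exception at 31.2 and 28.4 FPKM (log2 −0.14, q = 0.0673), and the 7 class I and peptide-loading genes a median of −0.21 with 6 called lower and Tap2 not called at 141 and 133 FPKM (log2 −0.083, q = 0.182). The lower calls of class I and peptide-loading genes were lost with the trend on expression level removed. The costimulatory receptor gene Cd40 fell from 731 to 329 FPKM (log2 −1.15, implied SE 0.059). Cd86 fell from 27.4 to 15.1 FPKM (log2 −0.86, implied SE 0.051), whereas Icosl rose from 23.1 to 30.2 FPKM (log2 0.39, implied SE 0.050). Markers of dendritic cells moved with this group. Of 4 tested, 3 fell and 1 rose, and the counts adjusted over the list alone were equal. Xcr1 fell from 0.529 to 0.114 FPKM (log2 −2.21, implied SE 0.23, damped −0.46). Ccr7 fell from 2.63 to 0.589 FPKM (log2 −2.16, implied SE 0.16, damped −1.19). Itgax fell from 26.6 to 19.9 FPKM (log2 −0.42, implied SE 0.048). Clec10a rose from 0.890 to 1.91 FPKM (log2 1.10, implied SE 0.26, damped 0.62), and the other 4 of these markers were too low for a test. Their median was −1.29, at percentile 0.01, but −0.42 at percentile 2.41 for genes of at least 1 FPKM, where Xcr1 is left out and Itgax becomes the middle value, and −0.43 on the log2(FPKM + 1) scale.

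Genes of alternative activation, scavenging and clearance of dead cells rose more often than they fell in the authors' deposited table. Of 18 tested, 10 were higher, 5 lower and 3 did not pass, with equal counts adjusted over the list alone. The list joins several themes, so these counts do not show that each of them rose. The median of 0.34 lay above all matched random lists, whose median was −0.062, and was 0.22 on the log2(FPKM + 1) scale. F13a1, which encodes the coagulation factor XIII A chain, rose from 1.44 to 8.22 FPKM (log2 2.51, implied SE 0.085). The scavenger receptor gene Stab1 rose from 22.7 to 59.8 FPKM (log2 1.4, implied SE 0.056). The complement gene C1qa rose from 12.7 to 20.4 FPKM (log2 0.68, implied SE 0.067). Il4ra, the interleukin-4 receptor gene, fell from 25.4 to 15.6 FPKM (log2 −0.70, implied SE 0.048), and Mrc1 stood at log2 −0.37. Axl fell from 163 to 108 FPKM (log2 −0.59, implied SE 0.057). Msr1 was not called at 371 and 389.6 FPKM (log2 0.070, q = 0.486), and was called higher with the trend on expression level removed. Of 10 macrophage markers 4 rose, 2 fell and 4 did not pass, unchanged when adjusted over the list alone. These were more rises than in matched lists (mean 1.16, percentile 98.8) and fewer falls (mean 5.30, percentile 1.67). Their median of −0.037, with a mean of 0.042, lay inside the central 95% at percentile 92.3. The median was −0.012 when centred and 0.097 with the trend on expression level removed, with 5 higher and 1 lower. The protease gene Ctss fell from 1398 to 984 FPKM (log2 −0.51, implied SE 0.067). Lgals3 was not called at 1679.7 and 1514 FPKM (log2 −0.15, q = 0.128).

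**Figure D2:**
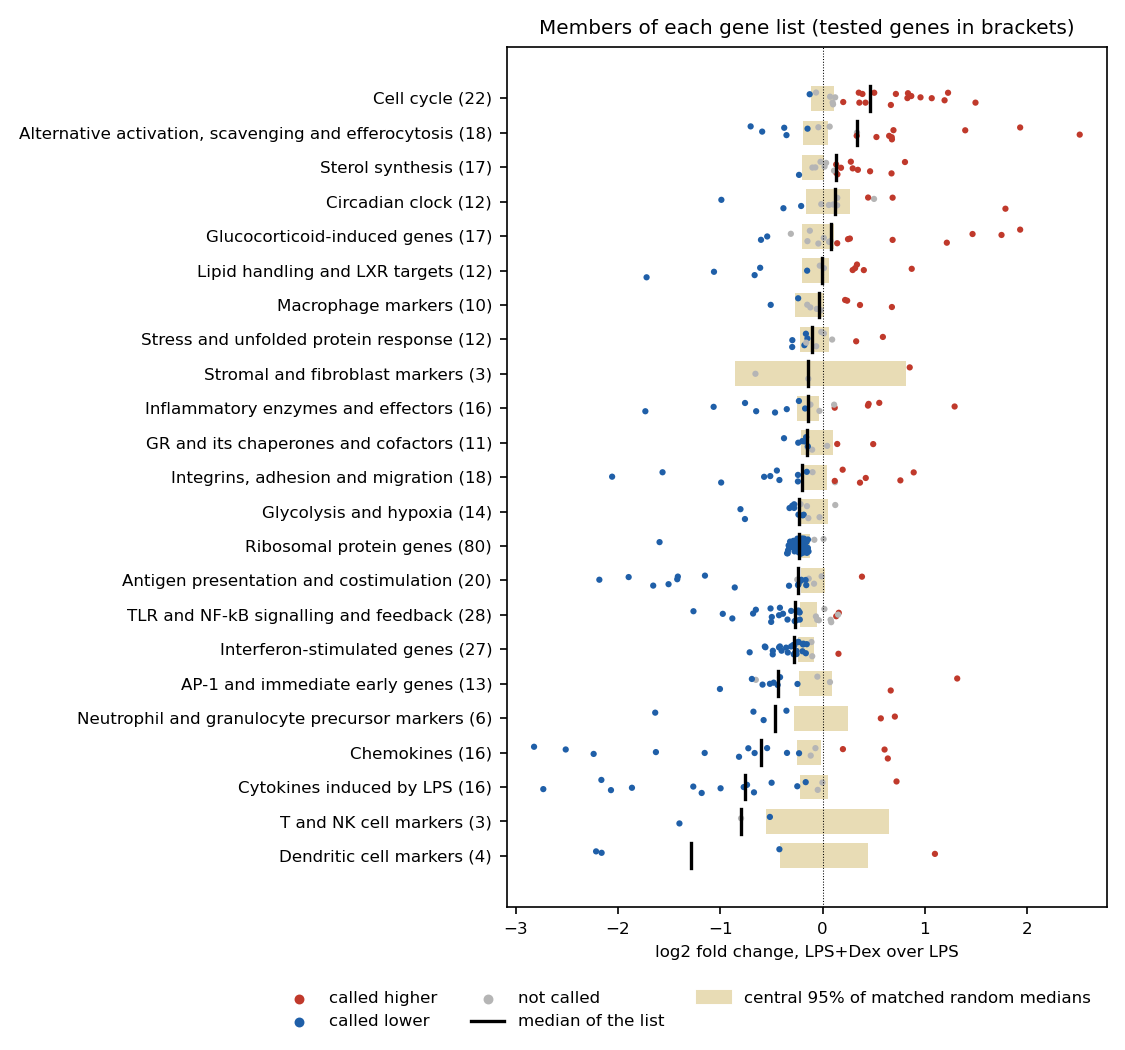
Log2 fold change of LPS+Dex over LPS (horizontal axis) of every tested member of each gene list with at least 3 tested members, from the authors' deposited table. Points are genes coloured by call, black bars are list medians and shaded boxes hold the central 95% of medians of matched random lists; the cell cycle median of 0.46 and the chemokine median of −0.60 lie outside their boxes on opposite sides.

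Cell cycle genes rose in the authors' deposited table, with 16 of 22 higher, 1 lower and 5 not passing, and equal counts adjusted over the list alone. The median of 0.46 lay above all matched random lists. The mitotic kinase gene Plk1 rose from 2.82 to 7.96 FPKM (log2 1.5, implied SE 0.079). The cyclin gene Ccna2 rose from 3.90 to 9.13 FPKM (log2 1.23, implied SE 0.088). The proliferation marker Mki67 rose from 19.8 to 31.5 FPKM (log2 0.67, implied SE 0.050). Of the replication helicase genes, Mcm6 was not called at 12.1 and 11.6 FPKM (log2 −0.063, q = 0.376). Pcna, the sliding clamp of DNA replication, fell from 226 to 207 FPKM (log2 −0.13, implied SE 0.049) (q = 0.0257), but was not called at −0.10 when centred on the median of genes with at least 1 FPKM and stood at 0.042 with the trend on expression level removed.

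Sterol synthesis genes rose modestly in the authors' deposited table, with 10 of 17 higher, 1 lower and 6 not passing, and equal counts adjusted over the list alone. The median was 0.13, at percentile 99.99 of matched random lists and 97.3 of unmatched ones. It was 0.26 with the trend on expression level removed, with 13 higher and 0 lower. Dhcr7, which catalyses the last step of cholesterol synthesis, rose from 3.06 to 5.36 FPKM (log2 0.81, implied SE 0.073). Fdps was not called at 250.1 and 270.4 FPKM (log2 0.11, q = 0.0837), although centred on the median of genes with at least 1 FPKM it was called higher at 0.14. Lipid handling and LXR target genes split evenly, with 5 of 12 higher, 5 lower and 2 not passing, also when adjusted over the list alone, a median of −0.0066 and percentile 80.1. The rises outnumbered those of matched lists (mean 1.88, percentile 98.3), and the median was 0.018 when centred and 0.017 with the trend on expression level removed. The lipoprotein gene Apoe rose from 715 to 1309 FPKM (log2 0.87, implied SE 0.068). The cholesterol exporter gene Abcg1 fell from 31.0 to 9.41 FPKM (log2 −1.72, implied SE 0.048). Srebf1 was not called at 15.4 and 15.6 FPKM (log2 0.014, q = 0.867). Lpl was listed at 0 in LPS and at 721 FPKM in LPS+Dex.

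Of 14 tested glycolysis and hypoxia genes in the authors' deposited table, 9 fell and 5 did not pass, and adjusted over the list alone, 10 fell. The test of Pfkfb3 failed, so it is not in these counts, although its value was higher in LPS+Dex (114 FPKM in LPS and 145 in LPS+Dex). Hif1a, which encodes the oxygen-regulated subunit of the hypoxia-inducible factor, fell from 44.8 to 25.7 FPKM (log2 −0.80, implied SE 0.047). The hexokinase gene Hk2 fell from 13.6 to 8.03 FPKM (log2 −0.76, implied SE 0.050). Pgk1 was not called at 715 and 649.6 FPKM (log2 −0.14, q = 0.0677). The median of −0.23 lay at percentile 3.3, just inside the central 95%, and at 1.54 on the log2(FPKM + 1) scale, 1.18 for genes of at least 1 FPKM, 1.99 with the trend on expression level removed (median −0.13) and 0.59 against unmatched lists. The falls outnumbered those of matched lists (mean 5.57, percentile 97.7). Of 18 integrin, adhesion and migration genes, 6 rose, 10 fell and 2 did not pass, as when adjusted over the list alone, with a median of −0.20 at percentile 4.35. This was 1.18 for genes of at least 1 FPKM and 0.62 against unmatched lists, but 10.9 with the trend on expression level removed (median −0.062). The chemokine receptor gene Ccr2 fell from 2.44 to 0.586 FPKM (log2 −2.06, implied SE 0.12, damped −1.12). The adhesion gene Vcam1 fell from 13.5 to 6.80 FPKM (log2 −0.99, implied SE 0.056). Icam1 was not called at 457 and 497 FPKM (log2 0.12, q = 0.127), though it was called higher with the trend on expression level removed.

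Circadian clock genes in the authors' deposited table had no common direction, with 3 of 12 higher, 3 lower and 6 not passing, also when adjusted over the list alone, and a median of 0.12 at percentile 77.4. That median was 0.065 on the log2(FPKM + 1) scale, 0.046 for genes of at least 1 FPKM and 0.060 with the trend on expression level removed. Per2 rose from 0.129 to 0.446 FPKM (log2 1.79, implied SE 0.20, damped 0.36). Bhlhe40 fell from 1.57 to 0.793 FPKM (log2 −0.99, implied SE 0.12, damped −0.52). Clock was not called at 3.18 and 3.42 FPKM (log2 0.10, q = 0.146). Among 11 genes of the receptor, its chaperones and cofactors, 2 rose, 6 fell and 3 did not pass, against 2 and 7 adjusted over the list alone; the median was −0.15, at percentile 9.96, and −0.051 with the trend on expression level removed. The coactivator gene Ncoa3 fell from 18.2 to 14 FPKM (log2 −0.38, implied SE 0.048). The chaperone gene Hsp90ab1 was not called at 423 and 395 FPKM (log2 −0.10, q = 0.184). Of 12 stress and unfolded protein response genes, 2 rose, 5 fell and 5 did not pass, equally when adjusted over the list alone, with a median of −0.10 at percentile 32.1; with the trend on expression level removed, the median was −0.0058, 4 were higher and 2 lower. Herpud1 rose from 9.49 to 14.3 FPKM (log2 0.59, implied SE 0.062). Hspa1a fell from 28.4 to 23.1 FPKM (log2 −0.30, implied SE 0.049). Hsp90b1 was not called at 211 and 209.5 FPKM (log2 −0.013, q = 0.884), though it was called higher after that removal.

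Several markers of other marrow cells changed in the authors' deposited table. Many others were too low for a test, namely 6 neutrophil, 8 T and NK cell, 6 B cell and 6 stromal markers. The calls rest on few genes and were not read as a change in cell content. Of 6 tested neutrophil and granulocyte precursor genes, Ltf fell from 0.448 to 0.144 FPKM (log2 −1.64, implied SE 0.28, damped −0.34). Camp, Ngp and S100a9 also fell, whereas Mmp8, from 4.35 to 7.10 FPKM (log2 0.71, implied SE 0.070), and S100a8 rose; all 6 calls stood when adjusted over the list alone, and the median of −0.46 lay at percentile 0.29. Of 3 tested T and NK cell markers 2 fell, also when adjusted over the list alone, with a median of −0.80 at percentile 0.89, or −0.17 at percentile 3.87 on the log2(FPKM + 1) scale. Lck fell from 5.01 to 1.90 FPKM (log2 −1.4, implied SE 0.096). Cd4 fell from 0.50 to 0.350 FPKM (log2 −0.51, implied SE 0.19, damped −0.15). Cd2 was not called at 0.348 and 0.200 FPKM (log2 −0.80, q = 0.116). Of the B cell markers tested, Cd22 fell from 0.733 to 0.461 FPKM (log2 −0.67, implied SE 0.18, damped −0.25) and Cd79b was not called at 0.132 and 0.131 FPKM (log2 −0.012, q = 0.989), with equal calls adjusted over the list alone. Of 3 stromal and fibroblast markers, Dcn rose from 0.389 to 0.703 FPKM (log2 0.85, implied SE 0.32, damped 0.29), a call that was lost with the trend on expression level removed, and Acta2 was not called at 0.268 and 0.243 FPKM (log2 −0.14, q = 0.775); the count adjusted over the list alone was equal, the mean was 0.019 and the median −0.14 at percentile 26.2, or −0.028 on the log2(FPKM + 1) scale and −0.26 with the trend on expression level removed. No erythroid, mast cell or basophil marker reached a test, their highest values being 0.0146 and 0.0183 FPKM. The globin genes Hba-a1 and Hbb-b1, which share rows with their copies, were also without a test, at 0.00419 and 0 FPKM in LPS. Of 23 lists with at least 3 tested members, 13 lay outside the central 95% of matched random lists, 3 above and 10 below. Lists of genes that vary independently would place 1.15 there. Genes of a list may vary together for any reason that sets the libraries apart, so the 13 are a description only.

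Ribosomal protein genes were lower almost throughout the authors' deposited table, with 75 of 80 called lower and 5 not passing, equally when adjusted over the list alone. The median was −0.23 against −0.17 for matched random lists, at percentile 0.13. It was −0.047 with the trend on expression level removed, with 11 lower. Rpl37 was not called at 148 and 140.4 FPKM (log2 −0.080, q = 0.178). The largest fall, of Rps27, from 24.9 to 8.26 FPKM (log2 −1.59, implied SE 0.41), is uncertain because a separate row joins Rps27 with the pseudogene Gm9846. That joined row had no test and was far higher, at 677 and 603 FPKM (log2 −0.17). Lower values of abundant genes were seen across all genes. Tested genes with a mean of 1 to 5 FPKM had a median log2 fold change of 0.050, with 694 higher and 542 lower of 3063. Those of 100 FPKM or more had a median of −0.18, with 77 higher and 474 lower of 774.

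**Figure D3:**
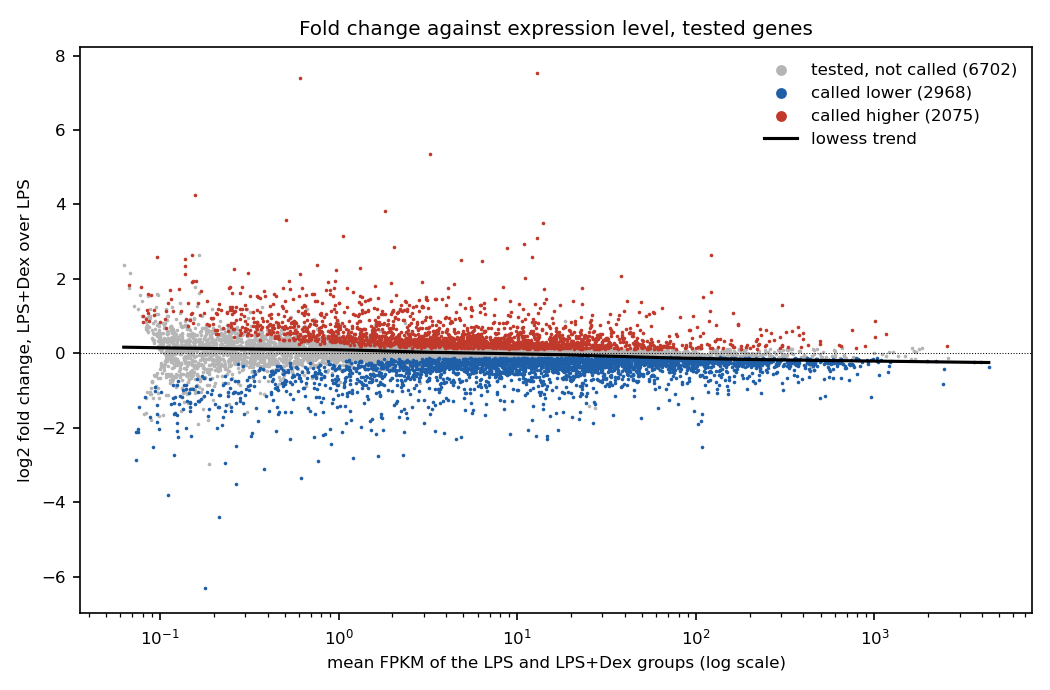
Log2 fold change of LPS+Dex over LPS (vertical axis) against the mean FPKM of both groups (horizontal log axis) for tested genes with both values above 0, from the authors' deposited table. Points are genes coloured by call and the black line is the lowess trend, which falls from above 0 for scarce genes to below 0 for abundant ones.

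The table marks 30 rows as not estimated and lists them at 0 in at least 1 group, among them Actb, Eef1a1, Lyz2 and Nos2 at 0 in both. Since these rows include genes that every cell uses, a 0 in them was read neither as absence nor as change.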

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

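The tests of a single scaling factor, of ribosomal protein genes, of loci with several rows, of dendritic cell markers and of class II against class I genes were chosen only after the result was seen. The tests of transcript length, GC content and an upper limit on fragments were written before their results were seen.

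A first set of results drew attention because a strong value in LPS+Dex stands beside a 0 in LPS, in rows the authors' deposited table does not test. The LPS+Dex values were 7833 FPKM for Ccl5, 2793 for Il1b, 1348 for Prdx1, 1074 for Il1rn, 721 for Lpl, 563 for Clic4 and 246 for Ptgs2. The opposite held for Clec4e, listed at 1286 FPKM in LPS and at 0 in LPS+Dex, and for Tnfrsf1b, at 749 and 0.

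The 30 rows listed at 0 in at least 1 group come from 27 loci. They were at 0 in both groups in 19 rows, in LPS alone in 9 and in LPS+Dex alone in 2. For the 9 loci with a value in 1 group, FPKM times transcript length lay at a median percentile of 99.9 among tested genes (range 99.0 to 99.97). This cannot decide on an upper limit on fragments per locus, because the loci drew attention by their strong values, and up to 117 tested genes ranked above such a locus. The ranked values also come from the group that was estimated, so they do not bear on the group listed at 0. In 3 of 3 loci that hold several of these rows the zeros fell in the same group or groups, as zeros set per locus rather than per gene would give. Only rows already marked as not estimated were compared, so this cannot decide between the 2. All of these rows carry the status HIDATA, a name that would go with such a limit, but its rule is not given in the sources used here. A limit on fragments stays open and no biological explanation was tested, so no direction was read for Il1b, Ccl5 or Ptgs2.

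Abundant genes were lower and scarce genes higher in LPS+Dex, with a slope of −0.107 log2 per 10-fold of mean FPKM (bootstrap SE 0.0073, 9386 genes, across genes, which are not independent replicates). Removing a trend on transcript length left 102% of the slope and removing a trend on GC content 101%, which argues against both as the source of this slope. GC content was itself related to the fold change across genes (Spearman rho 0.19, against −0.039 for transcript length). Its part in other differences between the groups therefore stays open. A single scaling factor between the groups would shift all levels alike, but the median of genes at 100 FPKM or more lay below that of genes at 1 to 5 FPKM (difference −0.23, SE 0.0103). A fall of abundant LPS-response genes does not account for the ribosomal protein genes, which lay below all genes of at least 1 FPKM (difference −0.21, SE 0.0086). The fall of ribosomal protein genes was known before this test was chosen and exceeded that of matched random lists (median −0.23 against −0.17). It therefore cannot decide on the other abundant genes. A difference in library preparation or depth and a broad response to Dex both stay open and untested, because the table has no values per library.

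MHC class II genes had a median log2 fold change of −1.46. Fewer dendritic cells in the LPS+Dex cultures are a possible explanation left open, with 3 of 4 tested dendritic cell markers lower and a median of −1.29. That median rests on few genes, being −0.42 for genes of at least 1 FPKM, where Xcr1 alone is left out, and −0.43 on the log2(FPKM + 1) scale. Clec10a rose, and both Clec10a and Itgax are also expressed by macrophages. Outside the fixed list, Cd207 rose and Ly75 fell (log2 −0.84). Both are expressed by dendritic cells and were brought in after their values were seen, so they do not decide. Lower Ciita (−2.18, or −0.85 on the log2(FPKM + 1) scale) is another candidate explanation, with class II genes below class I and peptide-loading genes by a difference of medians of −1.25, left open by H2-DMa, which at −0.14 was not below all class I genes, and by Ciita being expressed by dendritic cells as well. The 2 cannot be told apart here, and neither can be parted from an effect of Dex within the macrophages.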

How the results depend on the processing

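The alternatives that remove a trend on expression level, transcript length or GC content were chosen after seeing the data. No paired analysis was possible because the table gives 1 value per group, and for that reason leaving out each replicate, quantile normalization and other splits of the samples were not run either. Whether other groupings of the samples give as many calls was therefore not tested.

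The 2077 higher and 2968 lower genes became 884 and 1540 with Bonferroni adjustment, 589 and 646 at 1.5-fold or more, and 262 and 260 at 2-fold or more, as stricter limits must lower counts. With at least 5 FPKM in a group, where fewer genes are tested, 1114 were higher. All other alternatives kept both counts within 1.5 times. The share of lower calls, 58.8%, went both ways. It was 67.0% with at least 5 FPKM in a group (1114 higher, 2261 lower) and 63.5% with Bonferroni adjustment. It was 53.1% when centred on the median (2363 and 2676), 52.3% with the expression trend removed (2225 and 2441) and 49.8% at 2-fold or more. The number of lists outside the matched range was 13 and ranged from 13 to 15. Of 89 genes chosen for naming with a fold change, 65 were called. With the expression trend removed, 2 of the called genes reversed, Tnf to 0.045 and Pcna to 0.042, because the trend at their level exceeds their fall. Of the 24 genes not called, 11 changed sign there and 3 when centred. With the trend removed 8 of the 89 gained a call and 3 others lost theirs, and when centred 1 gained and 2 lost a call. On the log2(FPKM + 1) scale 43 moved by at least their implied SE, all toward 0, and 29 were smaller by over 1.5 times, since the added 1 shrinks changes of scarce genes. Unknown depth limits all of this, since precision per library cannot be given.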

Other observations

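The gene families in this part were found by a scan chosen after the values were seen, and their genes were named after it. Of 199 families by symbol stem, 2 had medians in the top 0.5% of matched random lists and 11 in the bottom 0.5%. Genes that vary independently would give 0.995 on each side. Genes of a family may vary together, and some families repeat genes of the fixed lists, so these counts are a description only. In the authors' deposited table, 15 of 29 tested kinesin genes of the Kif stem rose, 7 fell and 7 did not pass, with a median of 0.39 above all random lists. On the log2(FPKM + 1) scale the middle gene was Kif7 at 0.11. The largest rise was that of Kif18b, a kinesin of the mitotic spindle, from 0.512 to 1.72 FPKM (log2 1.75, implied SE 0.14, damped 0.85), and 2 further spindle kinesins that rose were Kif20a, from 1.61 to 3.85 FPKM (log2 1.26, implied SE 0.13), and Kif11, from 1.54 to 3.64 FPKM (log2 1.24, implied SE 0.074). The falls were led by Kif1a, from 0.231 to 0.0960 FPKM (log2 −1.27, implied SE 0.24, damped −0.17), and Kif5c, from 1.0 to 0.518 FPKM (log2 −0.95, implied SE 0.099, damped −0.40), motors of cargo transport.

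Of 8 genes of the Ms4a family of membrane proteins, 5 rose and 1 fell, with a median of 0.41 at percentile 99.95. Ms4a6d rose from 856 to 1150.0 FPKM (log2 0.43, implied SE 0.068) and Ms4a6b rose from 128 to 215 FPKM (log2 0.75, implied SE 0.051). Ms4a7 fell from 415 to 331 FPKM (log2 −0.33, implied SE 0.053). Of 10 TNF superfamily ligand genes, 7 fell and 2 rose, with a median of −0.52. On the log2(FPKM + 1) scale the middle genes were Tnfsf10 at −0.30 and Tnfsf13 at −0.28. Tnfsf13b, which rose, lost its call with the trend on expression level removed. Tnfsf4, which encodes the costimulatory ligand OX40L, fell from 18.6 to 4.45 FPKM (log2 −2.06, implied SE 0.073) and Tnfsf15 fell from 89.8 to 50.3 FPKM (log2 −0.84, implied SE 0.050). Tnfsf9, which encodes 4-1BBL, rose from 43.9 to 56.5 FPKM (log2 0.36, implied SE 0.051). Of 10 clade B serpin genes, 5 fell and 1 rose, with a median of −0.44. Serpinb2, an inhibitor of plasminogen activators, fell from 24.3 to 5.24 FPKM (log2 −2.21, implied SE 0.087). Serpinb1a, an inhibitor of neutrophil proteases, rose from 2.17 to 15.5 FPKM (log2 2.83, implied SE 0.089). Among 15 genes of the Clec symbol stem 7 fell and 2 rose, with a median of −0.37 at percentile 0.05. The stem leaves out other lectin genes, such as Cd207, which rose. On the log2(FPKM + 1) scale the middle gene was Clec4a1 at −0.14, and its call was lost with the trend on expression level removed. Clec7a, the beta-glucan receptor dectin-1, fell from 24.4 to 5.00 FPKM (log2 −2.29, implied SE 0.062).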
